A study of Zea mays with 4 samples.

How the data were processed

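Small RNA libraries of maize (Zea mays, cultivar VS-535) were analysed from 4 samples: immature embryos taken 15 days after pollination (IE, month 0 of culture) and embryogenic callus subcultured for 1 month (C1), 4 months (C4) or 10 months (C10). Each of these groups held 1 library, so no spread between replicates could be estimated and no p-value was computed for any difference between groups. Per the labels' protocols, total RNA was extracted with TRIzol, RNA of 18 to 30 nt was cut from a denaturing gel, and adaptors were ligated before reverse transcription, PCR and sequencing on a Genome Analyzer IIx. IE and C4 carried a different 3' adaptor from C1 and C10. IE was mixed with C1 for sequencing, and C4 with C10. Every pair of libraries therefore differed in the adaptor, in the sequencing mix or in both, and IE had no second embryo library to set beside it.

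Per the submitters' processing notes, reads were aligned with Bowtie 1.1.2 and the genome build was B73 RefGen_v4. The trimming, the quality filters, the mismatches allowed and the version of ShortStack, the program that defined small RNA loci, were not given in the sources used here. The authors deposited counts of clean reads by length from 18 to 27 nt, and the same values as RPM, that is, counts scaled to the clean reads of the library. They deposited counts of clean reads in 6 RNA classes and the same values as percent of the library. These classes were miRNA, trans-acting siRNA (tasiRNA), coding sequence (cdsRNA), long intergenic non-coding RNA (lincRNA), repeat-associated siRNA (rasiRNA) and other. No ribosomal, transfer, small nuclear or small nucleolar RNA class was analysed here. The deposited counts of mature miRNAs covered 252 entries of 27 families from 153 precursors, and the deposited RPM of these entries matched the counts divided by the clean reads.

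Members of a miRNA family often held the same or nearly the same counts, because a read had been counted for each member it matched. The sum of the miRNA table was 3.24, 4.02, 5.01 and 2.81 times the reads of the miRNA class in IE, C1, C4 and C10. A value for a member with a sequence shared by other members is therefore a value for that sequence. Entries of a family with identical counts in the 4 libraries were collapsed, which left 189 entries. Per the file headers, the ShortStack table gave the position of each locus, its read count, the fraction of reads on the top strand, a phase score, the most frequent RNA and the read counts by length. The headers named no library, so the values were taken as pooled over all libraries. The ShortStack table compares no groups, and how reads with several genome matches were placed was not given in the sources used here. A deposited list of the positions of loci with a called size was not used, since it held no further values. The gene table of the assembly Zm-B73-REFERENCE-NAM-5.0 was used for names alone, and 143 of the 153 precursors were found among its synonyms. No genome sequence or gene annotation of the authors' build was used.

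Levels of miRNAs were expressed as RPM. For each of the 6 pairs of libraries, the ratio of the RPM values was taken after 0.5 had been added to each count, for entries with a summed count of at least 20 in the pair. A miRNA was called higher or lower where this ratio was at least 2-fold in either direction, and log2 ratios are given on this basis. Folds of single miRNAs are printed as plain ratios of the RPM values, without the added 0.5, which differ from the former at low counts. Each ratio is given with an exact conditional 95% interval from its counts, each share of reads with a 95% Wilson interval, and the ratio of read lengths with an exact 95% interval. These intervals cover counting error only and not the spread between samples, since each group held 1 library. They treat reads as independent, which PCR copies without molecular identifiers are not, so they may be too narrow. Where a count was 0, the fold was computed against a floor of 3 counts per library and is printed as "at least". It is a lower bound with respect to the 0 count only, since the other count entered as counted. The exact interval can reach lower, as for miR162-3p in C4 against IE (30.2-fold against the floor, lower end 22.6). That floor was 1.39 RPM in IE, 1.47 RPM in C1, 5.71 RPM in C4 and 0.203 RPM in C10. Because the share of miRNA reads differed between libraries, each log2 ratio was also set against the median log2 ratio of all miRNAs compared in its pair, a value that the choice of scaling does not move apart from the added 0.5.

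The 5 lists of miRNA families, the naming rule and most alternatives were fixed before the data were examined. Most tests of technical explanations were chosen after their results had been seen. The lists held 29 families, of which 27 were in the table; miR482 and miR2118 were not analysed here. A family's level was the sum of its entries, and a list's median log2 ratio was placed among those of 10000 random lists of as many families of similar mean level, as a description of these libraries. Named miRNAs were the 10 most abundant, the 10 highest and 10 lowest ratios of C1 to IE, and the 5 highest and 5 lowest of each other pair, among entries with a summed count of at least 100. The most abundant entry of each family in the lists was named too. Named loci were the 5 with the most reads, the 5 with the most reads among those called as miRNA loci, and the 5 with the highest phase scores. Single miRNAs outside this rule were chosen after their values were seen, and this is said where they occur.

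The alternatives scaled the counts to the sum of the miRNA table, by median-of-ratios size factors as in DESeq2 1.42.0, by TMM factors as in edgeR 4.0.16, or, as a choice made after seeing the data, to the reads of the miRNA class. Others removed the minimum count or set it at 100, added 1 RPM in place of 0.5 counts, kept all deposited entries, or required the counting interval to exclude a ratio of 1. Chosen after seeing the data were 1 entry per family and arm, thinning all libraries to the reads of C4, and counts over C1 and C10 alone. Rank correlations between libraries were taken over 144 collapsed miRNAs with at least 20 counts over the 4 libraries, and their differences were bootstrapped over 26 families in 1000 draws. The code was tested on simulated data, drawn from the real libraries' means and depths with 40 of 189 entries changed by 3-fold or 8-fold in 100 simulations per pair. For C1 against IE it called 96.4% of the 3-fold and 99.9% of the 8-fold changes and 1.18% of the unchanged entries, and 95.2% of the intervals held the true ratio. For C10 against C4, the pair with the largest difference in depth, the values were 91.2%, 96.5%, 5.62% and 96.7%. The simulated libraries differed by counting error and the set changes alone, so these values are no error rates for the calls in the real libraries. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3.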

Results

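Small RNAs were sequenced from immature maize embryos 15 days after pollination (IE) and from embryogenic callus, a proliferating tissue able to form embryos, after 1 month (C1), 4 months (C4) and 10 months (C10) of subculture. The plants were of the cultivar VS-535, of the Tuxpeño type. Each group held 1 library, so none of the differences below has a replicate check. IE held 2165410 clean reads, C1 held 2042336, C4 held 525478 and C10 held 14808607. C10 thus gave 75.8% of the 19541831 reads, and values from C4 carried the widest counting intervals. IE and C4 shared a 3' adaptor, as did C1 and C10, whereas IE and C1 shared a sequencing mix, as did C4 and C10. The comparisons addressed which small RNAs differ between the embryo and the callus derived from such embryos, and between callus of different ages in culture.

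Reads of 24 nt, the usual length of heterochromatic siRNAs, were the most frequent in 3 libraries. They made up 28.6% (95% interval 28.5–28.7) of the reads of IE, 34.3% (34.3–34.4) of C1 and 44.1% (44.1–44.2) of C10, but 15.6% (15.5–15.7) of C4. In C4 the most frequent length was 22 nt, at 30.7% (30.6–30.8), against 19% in IE, 26.5% in C1 and 26.1% in C10. The share of 21 nt reads, the usual length of miRNAs, lay between 15.7% in IE and 19.7% in C4. The ratio of 24 nt to 21 nt reads was 1.82 (1.81–1.83) in IE, 2.0 (1.99–2.01) in C1, 0.792 (0.785–0.799) in C4 and 2.31 (2.30–2.31) in C10. Reads of 23 nt were 15.5% in IE and between 3.31% and 6.31% in the callus libraries. Reads outside 20 to 24 nt, which can hold breakdown products of longer RNA, were 12.0% in IE, 10.6% in C1, 19.8% in C4 and 2.95% in C10. In C4, reads of 18 nt alone were 13.9%.

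**Figure D1:**
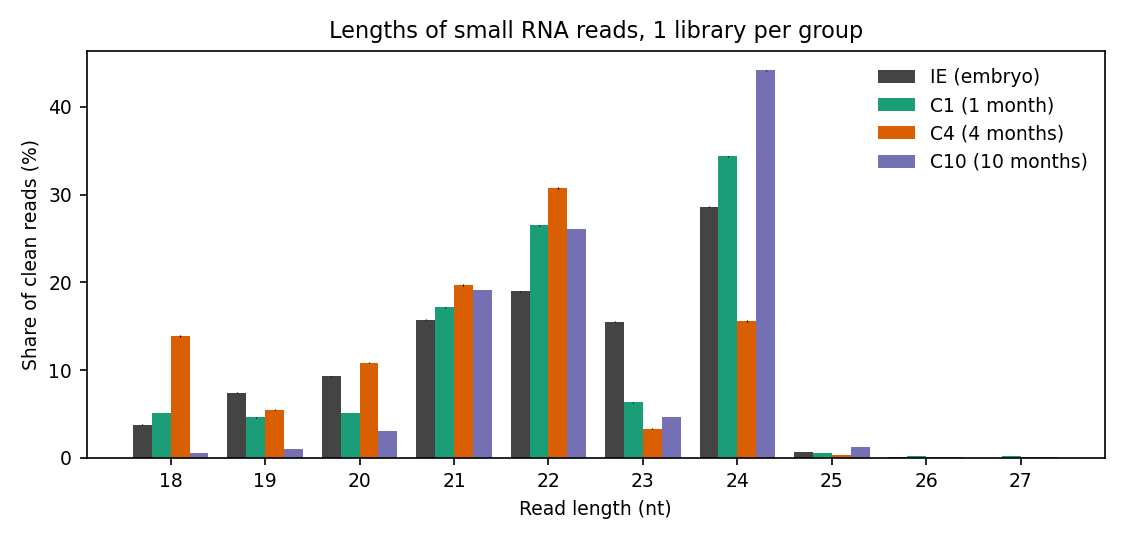
Share of clean reads (%) at each read length (nt) in the embryo library and the 3 callus libraries. Bars are single libraries and error bars are 95% Wilson intervals; the 24 nt bar was the highest in IE (28.6%), C1 (34.3%) and C10 (44.1%), and the 22 nt bar in C4 (30.7%).

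The share of miRNA reads was higher in each callus library than in IE. It was 3.44% (3.42–3.46) in IE, 7.04% (7.01–7.08) in C1, 17.0% (16.9–17.1) in C4 and 15.0% (15.0–15.0) in C10, or 2.05-fold, 4.95-fold and 4.35-fold the value of IE. Reads from coding sequences were 10.3% in IE, 6.54% in C1, 6.39% in C4 and 4.51% in C10. The tasiRNA share was highest in C1, at 0.339% (0.331–0.347), against 0.0414% (0.0388–0.0442) in IE, 0.0775% (0.0703–0.0853) in C4 and 0.0588% (0.0576–0.0601) in C10. Trans-acting siRNAs are phased RNAs whose production a miRNA sets off. Repeat-associated siRNAs took nearly the same share of each library, from 25.6% in C1 to 26.8% in C4. The lincRNA share was 15.2%, 15.0%, 11.7% and 12.4% in IE, C1, C4 and C10, and reads in none of these classes were 45.3%, 45.6%, 38.0% and 41.7%.

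**Figure D2:**
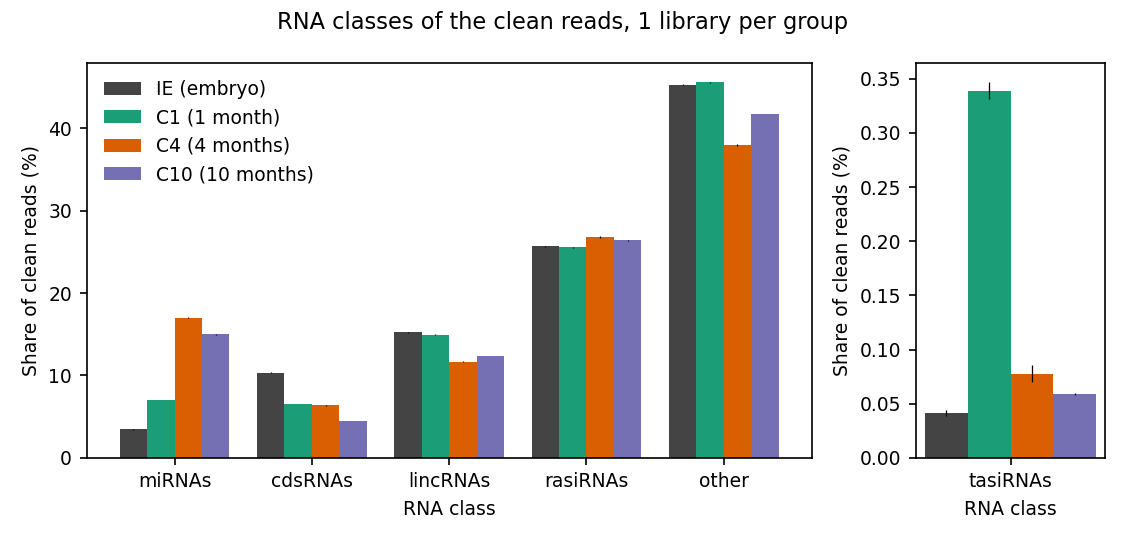
Share of clean reads (%) in each RNA class, with tasiRNAs on an axis of their own. Bars are single libraries and error bars are 95% Wilson intervals; the miRNA share was 3.44% in IE and 17.0% in C4, and the tasiRNA share was 0.339% in C1 and 0.0775% in C4.

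The most abundant miRNA was miR528b-5p, a monocot miRNA directed at transcripts of copper-containing oxidases, with 12003 RPM in IE, 5734 in C1, 45785 in C4 and 72115 in C10. Its near-identical entry miR528a-5p had almost the same levels. Next came miR156b-5p and 6 further entries of its family (miR156a, c, d, e, f and l), whose targets are SPL transcription factors. For miR156b-5p the levels were 2472, 5137, 46278 and 7376 RPM in IE, C1, C4 and C10. The level of miR159b-3p, directed at MYB transcripts, was 3548, 18778, 6897 and 10893 RPM. At the other end, miR2275a-5p, a trigger of reproductive phased siRNAs, had 1 read in C4, 1 in C10 and none in the others, and miR1432-5p had at most 31 reads in a library. No fold is given for miR2275, and for miR1432-5p the counting intervals of all 6 ratios included 1.

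**Figure D3:**
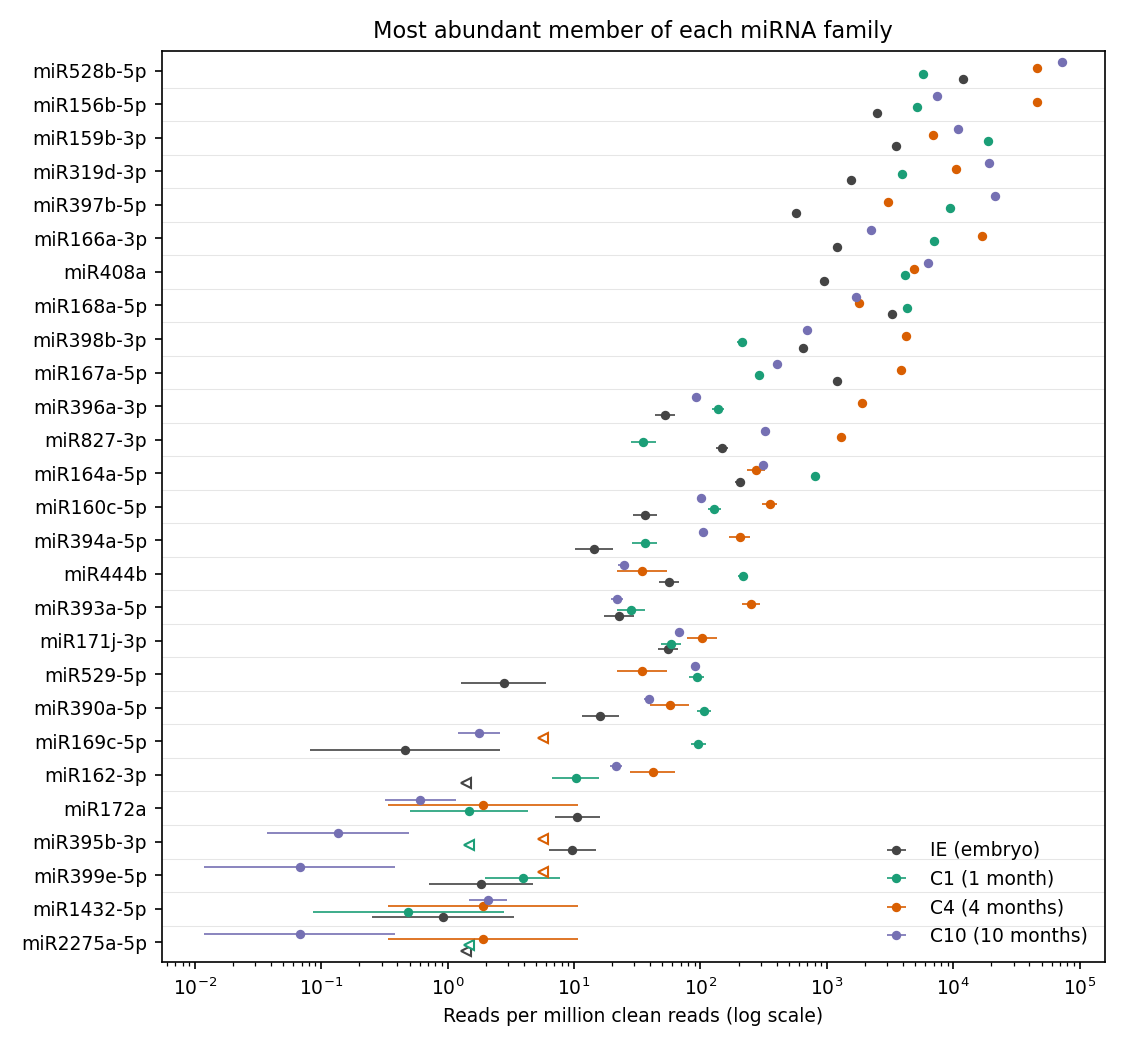
Level of the most abundant entry of each of the 27 miRNA families in RPM (log axis). Points are single libraries with 95% Wilson intervals and open triangles mark the floor of 3 counts where no read was counted; miR528b-5p reached 72115 RPM in C10 and 5734 RPM in C1.

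C1 against IE set callus after 1 month beside the embryo; these libraries shared the sequencing mix and differed in the adaptor. Among entries with a summed count of at least 100, the largest ratio was that of miR164e-5p, a family that targets NAC transcription factors, at 729 RPM in C1 and 2.77 RPM in IE, 263-fold (121–718). The level of miR169c-5p was 208-fold higher in C1 (36.9–8249, 1 read in IE), that of miR171h-5p 70.8-fold (27.3–262) and that of miR529-5p, which shares SPL targets with miR156, 33.6-fold (15.1–92.6). The 3p strands of miR156, the strands opposite the mature miRNA, went both ways. Those of miR156d and miR156g were 22.3-fold higher in C1 (18.5–27.1) and that of miR156f 22.2-fold. Those of miR156i, miR156l, miR156e and miR156h were lower in C1 by 94.6-fold (49.6–208), 57.0-fold (37.1–92.4), 13.7-fold (8.0–25.6) and 11.4-fold (7.97–16.8). MiR156k-5p was 30.0-fold and miR164f-5p 13.7-fold higher. Also lower were miR168b-3p by 11-fold (9.16–13.2) and miR398b-5p by 3.16-fold (2.64–3.80).

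In the same comparison 56 of 126 miRNAs were at least 2-fold higher and 34 at least 2-fold lower, with a median log2 ratio of 0.57. The split was 25 higher and 57 lower when counts were scaled to the miRNA table, 42 and 44 with median-of-ratios factors, 27 and 52 with TMM, and 29 and 47 when scaled to the miRNA class reads. Of the 7 nutrient, copper and oxidative stress families, 3 were higher and 4 lower in C1, with a median log2 ratio of −1.07, 2.37 below the median of all families and at percentile 0.39 of random lists. MiR397b-5p, which targets laccases, was 16.4-fold higher (15.5–17.4) and miR408a 4.38-fold higher (4.17–4.59). MiR827-3p, of the phosphate response, was 4.17-fold lower (3.22–5.46) although its family sum was higher, miR398b-3p, which targets copper/zinc superoxide dismutases, 3.05-fold lower (2.74–3.41), and miR528b-5p 2.09-fold lower (2.05–2.14). MiR395b-3p, of sulfate assimilation, had 21 reads in IE and 0 in C1, at least 6.60-fold lower, and miR399e-5p had 4 and 8. MiR399 counted as lower through its family sum, 30 in IE and 13 in C1. The sum of miR395, 227 in IE and 0 in C1, was taken over entries that share reads. Among 10 families that target developmental transcription factors, 8 were higher and 1 lower (median log2 1.43, percentile 63.0). Of the higher sums, those of miR159, miR166 and miR529 stayed at least 2-fold higher on the miRNA table scale (log2 1.04, 1.09 and 2.49). Those of miR164 and miR169 fell within 2-fold (0.86 and 0.21), and those of miR156, miR171 and miR319 turned lower (−0.33, −0.34 and −0.0388). MiR166a-3p, which targets HD-ZIP III transcripts, was 5.89-fold higher (5.65–6.14), miR159b-3p 5.29-fold (5.16–5.42) and miR164a-5p 3.90-fold. MiR172a, directed at AP2 transcripts, had 3 reads in C1 and 23 in IE, 7.23-fold lower (2.18–37.6). The ratio of miR156b-5p, 2.08-fold higher, turned lower with the miRNA table and TMM scalings, and that of miR171j-3p (1.06) turned lower with all 3 planned scalings. MiR319d-3p was 2.56-fold and miR396a-3p 2.61-fold higher, 0.79 and 0.81 above the median miRNA on the log2 scale.

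Among the 4 auxin and tasiRNA families, 2 were higher in C1 and none at least 2-fold lower in the family sums (median log2 0.92, but −0.43 on the miRNA table scale, percentile 23.7). MiR390a-5p, which sets off tasiRNAs against auxin response factors, was 6.60-fold higher (4.61–9.73). MiR160c-5p was 3.52-fold higher (2.72–4.58), and miR393a-5p, which targets auxin receptors, had a ratio of 1.25 (0.843–1.87), which was below 1 in the 3 planned scalings. The entry miR167a-5p was 4.10-fold lower (3.75–4.49), 2.61 below the median miRNA on the log2 scale, with miR167b-5p and miR167c-5p alike. Of the silencing families, which target transcripts of Dicer-like and ARGONAUTE proteins, miR162-3p had 21 reads in C1 and 0 in IE, at least 7.42-fold higher. MiR168a-5p had a ratio of 1.31 (1.27–1.35), which was below 1 in the 3 planned scalings. MiR444b, which targets MADS-box transcripts, was 3.86-fold higher (3.15–4.75), and miR394a-5p 2.53-fold higher, with a turn to slightly lower on the miRNA table scale.

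C4 against IE, with a shared adaptor and different sequencing mixes, again had large ratios in miR156 and miR164. MiR156k-5p was 451-fold higher in C4 (251–905), miR164e-5p 92.0-fold (41.2–255), and the 3p strands of miR156d and miR156g 53.4-fold (44.2–65.1), with that of miR156f at 53.0-fold. The 3p strands of miR156h, miR156i, miR156e and miR156l were lower in C4 by 96.6-fold (17.2–3824, 1 read in C4), 24.3-fold (12.8–53.4), 24.8-fold (6.76–206, 2 reads in C4) and 14.7-fold (9.55–23.8), and miR167g-3p by 9.75-fold (4.41–26.8). Of 120 miRNAs, 69 were higher and 22 lower, with a median log2 ratio of 2.10. The split was 20 and 58 on the miRNA table scale, 52 and 41 with median-of-ratios factors, 20 and 56 with TMM, and 33 and 52 when scaled to the miRNA class reads. C4 was also the library with the fewest reads and with 19.8% of reads outside 20 to 24 nt, against 12.0% in IE.

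All 4 auxin and tasiRNA families were higher in C4 than in IE (median log2 3.31, 0.87 above the median of all families, percentile 84.9). On the miRNA table scale the sums of miR160, miR390 and miR393 had log2 ratios of 0.33, 0.42 and 0.43, and that of miR167 had −1.92. MiR393a-5p was 11.1-fold higher (7.94–15.7) and miR160c-5p 9.65-fold (7.38–12.7). MiR167a-5p, 3.24-fold higher, and miR390a-5p, 3.53-fold higher, lay 0.40 and 0.27 below the median miRNA and turned lower with the miRNA table and TMM scalings. Of the developmental families, 6 were higher and 1 lower (median log2 1.91, but −1.03 on the miRNA table scale, percentile 31.8). MiR396a-3p was 36.0-fold higher (29.6–44.1), miR156b-5p 18.7-fold (18.2–19.3), miR166a-3p 13.9-fold (13.3–14.6) and miR529-5p 12.4-fold (4.70–38.0). MiR159b-3p (1.94-fold), miR164a-5p (1.34-fold) and miR171j-3p (1.85-fold) turned lower with every planned scaling, and miR319d-3p (6.86-fold) with the miRNA table and TMM. In the nutrient list 5 families were higher and 2 lower (median log2 2.37, but −0.57 on the miRNA table scale, percentile 41.5). MiR827-3p was 8.85-fold higher (7.74–10.1). MiR398b-3p (6.49-fold), miR397b-5p (5.28-fold), miR408a (5.16-fold) and miR528b-5p (3.81-fold) were higher in RPM and lower with the miRNA table and TMM scalings. MiR395b-3p had 0 reads in C4, at least 1.70-fold lower, and miR172a had 1 read, 5.58-fold lower (0.906–230). MiR162-3p had 22 reads in C4, at least 30.2-fold higher, and miR168a-5p was 1.82-fold lower (1.70–1.95). MiR394a-5p was 14.2-fold higher (9.46–22), and the ratio of miR444b was 0.608 (0.349–1.00).

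C10 against IE shared neither adaptor nor sequencing mix. MiR156k-3p had 554 reads in C10 and 0 in IE, at least 27-fold higher. MiR397a-5p was 115-fold higher (86.7–156), miR164e-5p 54.7-fold (25.1–149), miR162-3p at least 15.4-fold and miR171h-3p at least 6.87-fold. The 3p strands of miR156i, miR156l, miR156e and miR156h were again far lower, by 238-fold (161–366), 119-fold (93.9–153), 107-fold (61.4–205) and 90.7-fold (62.6–136), and miR159c-3p was 22.3-fold lower (17.2–29.3). Of 139 miRNAs, 65 were higher and 39 lower in C10 (median log2 0.88). The split was 28 and 71 on the miRNA table scale, 42 and 48 with median-of-ratios factors, 40 and 50 with TMM, and 26 and 74 when scaled to the miRNA class reads. Reads outside 20 to 24 nt were 2.95% in C10 and 12.0% in IE.

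In the nutrient list 4 families were higher in C10 than in IE and 1 lower (median log2 2.07, 1.09 above the median of all families, percentile 85.0). MiR397b-5p was 37.3-fold higher (35.3–39.5), miR408a 6.63-fold (6.35–6.93) and miR528b-5p 6.01-fold (5.93–6.08), each in the same direction under the 3 planned scalings. MiR827-3p (2.19-fold) turned lower on the miRNA table scale and miR398b-3p (1.07-fold) in the 3 planned scalings. MiR395b-3p was 71.8-fold lower (17.6–632, 2 reads in C10). MiR399e-5p was 27.4-fold lower (2.71–1347), but with 1 read in C10 and 4 in IE it was below the minimum count. The family sum of miR399, 122 in C10 and 30 in IE, was within 2-fold, with a ratio of 0.595 (0.396–0.919). Of the developmental families 5 were higher and 2 lower (median log2 0.98, but −0.94 on the miRNA table scale, percentile 40.5). MiR529-5p was 32.5-fold higher (14.9–88.7) and miR319d-3p, which targets TCP transcripts, 12.4-fold (12.0–12.8). MiR159b-3p (3.07-fold) and miR156b-5p (2.98-fold) turned lower on the miRNA table scale. MiR172a was 17.5-fold lower (7.79–42.9). MiR166a-3p (1.86-fold), miR164a-5p (1.53-fold), miR171j-3p (1.21-fold) and miR396a-3p (1.76-fold) were within 2-fold and turned lower in at least 1 of the planned scalings. In the auxin list, 2 families were higher and 1 lower (median log2 0.69, but −1.23 on the miRNA table scale, percentile 14.0). MiR167a-5p was 2.98-fold lower (2.84–3.12), miR160c-5p 2.78-fold and miR390a-5p 2.41-fold higher, with both turning lower on the miRNA table scale, and miR393a-5p had a ratio of 0.973 (0.719–1.34). MiR168a-5p was 1.93-fold lower (1.88–1.98), miR394a-5p 7.25-fold higher (5.09–10.7) and miR444b 2.29-fold lower (1.85–2.81).

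The entries that differed from IE in the same direction in all callus libraries numbered 30 higher and 15 lower of 119 compared. Independent lists of these sizes would share 12.7 and 1.90, but the 3 lists are not independent, since IE was the only embryo library and entered each of them. Simulated libraries that differed by counting alone gave at most 4 and 2 in 1000 simulations and leave out the spread between samples. No value expected without a tissue difference is therefore available, and the excess may come in part or in whole from the shared library. Each alternative scaling lowers every ratio of callus to IE, so a lower call could not be lost through it. Across the 5 scalings, all 15 lower entries, from 7 families, therefore kept their call, and 8 of the 30 higher entries, from 4 families, kept theirs. The higher ones were miR156k-3p, miR156k-5p, the 3p strands of miR156d, miR156f and miR156g, miR164e-5p, miR162-3p and miR167b-3p. The lower ones included the 3p strands of miR156e, miR156h, miR156i and miR156l, miR169o-5p, miR168b-3p, 3 entries of miR395 and miR172a. In C4 the calls of the miR395 entries, with 0 reads, rest on the added 0.5 (at least 1.62-fold to 1.70-fold lower against the floor), and the counting intervals of miR172a, miR167c-3p and miR166n-5p included 1. MiR169o-5p had 44.8 RPM in IE, no read in C1 or C4 and 0.0675 RPM in C10. Without C4, 35 were higher and 21 lower in both C1 and C10.

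C4 against C1 shared neither adaptor nor mix. MiR827-3p was 36.9-fold higher in C4 (28.9–47.7), the 3p strands of miR398a and miR398b 20-fold and 19.8-fold, and those of miR393a and miR393c 17.2-fold (11.4–26.6) and 16.5-fold. MiR169c-5p had 196 reads in C1 and 0 in C4, at least 16.8-fold lower. MiR166a-5p was 11.5-fold lower (9.10–14.8), miR167g-3p 11.1-fold (5.05–30.7), miR444a 8.55-fold (4.95–16.2) and miR444b 6.35-fold (3.97–10.8). Of 113 miRNAs, 67 were higher and 28 lower (median log2 1.42). The split was 36 and 38 on the miRNA table scale, 45 and 30 with median-of-ratios factors, 34 and 42 with TMM, and 43 and 37 when scaled to the miRNA class reads. Reads outside 20 to 24 nt were 19.8% in C4 and 10.6% in C1. In the auxin list 3 of 4 families were higher (median log2 1.70, percentile 71.0), with miR167a-5p 13.3-fold (12.1–14.6) and miR393a-5p 8.85-fold higher, and miR390a-5p 1.87-fold lower (1.27–2.84). The developmental list held 4 higher and 4 lower of 9 families (median log2 0.12, but −1.47 on the miRNA table scale and −0.82 with median-of-ratios factors, 1.21 below the median of all families, percentile 8.09). MiR396a-3p was 13.8-fold (12.1–15.8) and miR156b-5p 9.01-fold higher (8.80–9.22), whereas miR159b-3p was 2.72-fold, miR164a-5p 2.91-fold and miR529-5p 2.72-fold lower. MiR166a-3p (2.36-fold), miR319d-3p (2.68-fold) and miR160c-5p (2.74-fold) were higher but turned lower with the miRNA table and TMM scalings. In the nutrient list 3 of 5 families were higher and 1 lower (median log2 1.5, but −0.0902 on the miRNA table scale, percentile 76.3), with miR528b-5p 7.99-fold higher (7.81–8.16) and miR397b-5p 3.10-fold lower (2.95–3.27). MiR162-3p was 4.07-fold higher (2.14–7.78), miR168a-5p 2.38-fold lower (2.23–2.55) and miR394a-5p 5.62-fold higher.

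C10 against C1, with a shared adaptor and different mixes, had miR397a-5p 51.5-fold higher in C10 (42.4–63.3). MiR171d-5p and miR171e-5p, strands opposite miRNAs that target GRAS transcripts, were 24.9-fold (13.1–54.6) and 22.7-fold higher, miR398a-5p 15.2-fold and miR528a-5p 12.9-fold (12.6–13.1). MiR169c-5p was 54.7-fold lower (36.2–85.8), miR159c-3p 30.6-fold (23.7–39.8), miR167g-3p 22.4-fold (17.5–29.1), miR166a-5p 17.9-fold (16.8–19.1) and miR166c-5p 15.0-fold. Of 131 miRNAs, 35 were higher and 43 lower (median log2 −0.34), with 26 and 59 on the miRNA table scale, 35 and 40 with median-of-ratios factors, 37 and 39 with TMM, and 24 and 70 when scaled to the miRNA class reads. Reads outside 20 to 24 nt were 2.95% in C10 and 10.6% in C1. In the nutrient list 4 of 7 families were higher and none lower in the family sums (median log2 1.34, 1.18 above the median of all families, percentile 95.6). MiR395, with a summed count of 23 in C10 over entries that share reads and 0 in C1, counts among the 4 through the added 0.5, and with it at its bound the median was 0.77. MiR827-3p was 9.12-fold higher (7.23–11.7), miR398b-3p 3.27-fold (2.97–3.6) and miR397b-5p 2.28-fold (2.24–2.31). The developmental list had 1 family higher and 4 lower of 10 (median log2 −0.68, percentile 4.34), with miR319d-3p 4.84-fold higher (4.74–4.95) and miR166a-3p 3.16-fold (3.10–3.22) and miR164a-5p 2.55-fold lower. MiR172a, with 9 reads in C10 and 3 in C1, was below the minimum count (2.42-fold lower, 0.421–9.68). Its family counted as lower through its sum, 48 in C10 and 13 in C1. All 4 auxin families were within 2-fold by their sums, although miR390a-5p was 2.74-fold lower (2.34–3.21). MiR168a-5p was 2.53-fold lower (2.47–2.59), miR162-3p 2.08-fold higher (1.33–3.40), miR394a-5p 2.87-fold higher and miR444b 8.82-fold lower (7.66–10.2).

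C10 against C4, sequenced together with different adaptors, gave 19 higher and 70 lower of 132 miRNAs (median log2 −1.16). The split was 44 and 48 on the miRNA table scale, 44 and 48 with median-of-ratios factors, and 63 and 23 with TMM, so the direction of this balance depended on the scaling. Higher in C10 were miR398b-5p by 10.2-fold (7.56–14.1), miR528a-3p 11.4-fold (3.89–55.4, 3 reads in C4), miR397a-5p 9.57-fold (8.10–11.4), miR398a-5p 7.60-fold and miR397b-5p 7.06-fold (6.72–7.43), whereas miR398b-3p, the most abundant of miR398, was 6.06-fold lower (5.79–6.35). MiR396e-5p was 78.9-fold lower in C10 (51.5–124), miR159a-5p 24.8-fold (21.4–28.8), miR156k-5p 21.9-fold (20.3–23.6), miR396a-3p 20.4-fold (18.8–22.2) and miR166m-3p 16.3-fold (14.8–17.9). By family sums, the nutrient list had 2 families higher and 1 lower (median log2 0.68, 1.19 above the median of all families, percentile 98.3). By their most abundant entries 1 was higher, miR398b-3p and miR827-3p were lower and 2 were within 2-fold. The remaining entries, miR395b-3p (2 reads in C10, 0 in C4) and miR399e-5p (1 and 0), were below the minimum count. All 4 auxin families were lower by their sums (median log2 −2.31, percentile 13.0), with miR393a-5p 11.4-fold (9.25–14.0) and miR167a-5p 9.65-fold lower (9.17–10.1). The sums of miR160 and miR390 fell within 2-fold on the miRNA table scale (log2 −0.73 and −0.21) and turned higher with TMM (0.30 and 0.83). Those of miR167 and miR393 kept their direction. MiR390a-5p was 1.47-fold lower (0.981–2.12) and turned higher in the 3 planned scalings. In the developmental list 1 family was higher and 5 lower (median log2 −0.68, but 0.34 on the miRNA table scale and 0.36 with median-of-ratios factors, percentile 36.1), with miR166a-3p 7.47-fold (7.29–7.65) and miR156b-5p 6.27-fold lower (6.19–6.36). MiR827-3p (4.04-fold lower), miR160c-5p (3.47-fold lower) and miR162-3p (1.96-fold lower, 2.0-fold with the added 0.5) turned higher in at least 1 planned scaling. C4 had 525478 reads against 14808607 in C10, and 19.8% against 2.95% of reads outside 20 to 24 nt.

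The silencing list held miR162 and miR168. Its median log2 ratio was 2.88, 3.29 and 2.74 for C1, C4 and C10 against IE, where miR162 had no read, and 1.57, 1.99 and 1.44 with miR162 at its bound. Between callus libraries it was 0.42 for C4 against C1, −0.14 for C10 against C1 and −0.56 for C10 against C4, of which the first and the last turned to −1.17 and 0.46 on the miRNA table scale and to −0.53 and 0.48 with median-of-ratios factors. The list of other families compared miR394 and miR444, with miR1432 added in the pairs with C10, while miR2275 had too few reads. Its medians were 1.67, 1.51 and 0.32 for C1, C4 and C10 against IE, and −0.16, 1.53 and −0.29 for C4 against C1, C10 against C1 and C10 against C4. Those for C4 and C10 against IE and for C10 against C4 turned to −1.43, −1.60 and 0.73 on the miRNA table scale and to −0.16, −0.31 and 0.75 with median-of-ratios factors. These 2 lists lay between percentiles 36.0 and 84.3 of random lists.

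Across 144 miRNAs, which are not independent replicates, Spearman's rho between libraries was 0.813 for C1 and IE, 0.791 for C4 and IE and 0.755 for C10 and IE. Between callus libraries it was 0.880 for C4 and C1, 0.879 for C10 and C1 and 0.904 for C10 and C4. The mean rho was 0.835 for the pairs with the same adaptor, 0.859 for those with the same sequencing mix and 0.817 for those with neither.

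ShortStack defined 233926 small RNA loci on B73 RefGen_v4, holding 13539805 reads. These were taken as pooled over the libraries, since no library was named, and would then be 69.3% of the clean reads. Loci dominated by 24 nt reads were 195096, or 83.4%, and held 48.8% of the locus reads. Those of 22 nt were 5.72% of loci with 26.6% of reads, and those of 21 nt 2.55% of loci with 18.2% of reads. If the libraries were pooled, these values describe mainly C10, which gave 75.8% of the clean reads. The locus with the most reads, on chromosome 9 from 156643637 to 156643751, held 1101011 reads, or 8.13% of all locus reads, and 96.2% of them were UGGAAGGGGCAUGCAGAGGAG, miR528. A locus on chromosome 5 from 84609557 to 84610678 held 340387 reads, chiefly UUGAGCGCAGCGUUGAUGAGC, the sequence of miR397, and was not called a miRNA locus by ShortStack. Of the 66 loci called as miRNA loci, those with the most reads after miR528 were on chromosome 3 from 215788736 to 215788913 (241070 reads, UUGGACUGAAGGGUGCUCCCU, miR319) and from 25007830 to 25008061 (125301 reads, UUUGGAUUGAAGGGAGCUCUG, miR159). They were followed by chromosome 3 from 6928581 to 6928707 (102403 reads, UGACAGAAGAGAGUGAGCAC, miR156) and chromosome 8 from 10753090 to 10753305 (87889 reads, miR159). Whether these loci lie in exons or introns was not analysed here.

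The 5 loci with the highest phase scores, a measure of reads spaced in a regular register, were all dominated by 22 nt reads. The highest score was 897.3 on chromosome 3 from 213731035 to 213735490, a locus of 112347 reads of which 62.1% were 22 nt. The others lay on chromosome 2 from 225250700 to 225253572 (score 806.5), chromosome 5 from 1648901 to 1650519 (760.8), and chromosome 10 from 37082803 to 37091621 (699.2) and from 144928370 to 144932022 (634.3). Between 65.4% and 73.8% of the reads of these loci were 22 nt. Of the 62 loci with a phase score of at least 100, 57 were of the 22 nt class, whereas of the 375 with a score of at least 30, 182 were of the 22 nt and 185 of the 24 nt class.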

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

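For 5 miRNA families the most abundant entry lay at least 2-fold above IE in 1 callus library and at least 2-fold below IE in another, per the clean reads; these differences were not tested, since each group held 1 library. All tests in this part were chosen only after the result was seen. MiR827-3p had a log2 ratio to IE of −2.05 in C1, 3.14 in C4 and 1.13 in C10, so that C4 stood 5.20 above C1. MiR398b-3p had −1.61, 2.70 and 0.10, with C4 4.31 above C1, and miR528b-5p had −1.07, 1.93 and 2.59, with C10 3.65 above C1. MiR167a-5p had −2.04, 1.70 and −1.57, with C4 3.73 above C1. MiR444b had 1.94, −0.68 and −1.20, with C1 3.14 above C10. The signs stayed opposite in 4 of 4 scalings for miR444b, miR528b-5p and miR827-3p, and in 2 of 4 for miR167a-5p and miR398b-3p. On the miRNA table and TMM scales the higher value in C4 turned lower for miR167a-5p (−1.24 and −1.21), miR398b-3p (−0.24 and −0.21) and miR528b-5p (−1.01 and −0.97), whose opposite signs then rest on C10, while miR827-3p stayed slightly higher (0.21 and 0.24).

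MiR398b-3p, miR528b-5p and miR827-3p were lower in C1 than in IE, 2 libraries that shared the sequencing mix and differed in the adaptor. C10, with the adaptor of C1, lay above C1 by a log2 ratio of at least 2.61 over the 4 scalings for miR528b-5p and miR827-3p. The adaptor alone therefore does not set their levels across the libraries. Whether it lowered C1 against IE cannot be told, since C10 also differed from C1 in mix and culture age. For miR528b-5p, C10 above C1 was also part of the flag. For miR398b-3p the ratio nearest to 0 was 1.13 with an interval from 0.996. There too the adaptor cannot be told apart from a difference between tissues. As to the higher level in C4, which had the adaptor of IE, the mix alone would put C10 near C4, but the log2 ratios of C10 to C4 lay 3.26 apart, so no common scaling brings all 3 within 2-fold, although each alone came within it in at least 1 scaling (miR827-3p at 0.0387 with TMM) and stays open. For miR167a-5p, miR167b-5p, miR167c-5p and miR167d-5p, lower in C1 than in IE, the adaptor may account for the difference, since C10 lay within 2-fold of C1 in the 4 scalings (farthest from 0, 0.79). A difference between embryo and callus would put C10 near C1 as well. For miR167a-5p, C4, with the adaptor of IE, had log2 ratios to IE of 1.70 per the clean reads and 0.03 with median-of-ratios factors. They were −1.24 on the miRNA table scale and −1.21 with TMM. The 6 other 5p entries of miR167 had log2 ratios of C1 to IE from −0.64 to −0.25 per the clean reads and from −1.99 to −0.97 in the other scalings, with C10 below C1 (nearest to 0, −1.14), and a difference between callus ages stays open and untested throughout.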

How the results depend on the processing

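Chosen only after the data were seen were the scaling to the miRNA class reads, 1 entry per family and arm, the thinning of all libraries to the reads of C4, the counts over C1 and C10 alone, and the presentation of ratios relative to the median miRNA. No paired analysis was possible because each group held 1 library, and leaving out a library removes its group. Shares without ribosomal and transfer RNA were not run, and signs of RNA breakdown from these classes are missing, since the class table has neither class. The overlap of loci with genes was not run either, since no annotation of the build was at hand. Depth limits C4 the most, with a floor of 5.71 RPM against 0.203 RPM in C10, and detection of a rare miRNA in C10 alone is not read as its absence elsewhere. Where no cause is given below, the cause was not tested.

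The number of miRNAs at least 2-fold higher or lower stayed within 1.5 times its value in all 6 pairs when 1 RPM was added in place of 0.5 counts and when the counting interval had to exclude 1. Counts over C1 and C10 alone stayed within 1.5 times those over the 3 callus libraries, and the shares of each read length were the same from the deposited RPM.

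Among reads of 20 to 24 nt only, a smaller denominator by construction, the shares in IE, C1, C4 and C10 were 10.5%, 5.73%, 13.5% and 3.18% for 20 nt, 17.9%, 19.2%, 24.6% and 19.7% for 21 nt, 21.5%, 29.6%, 38.3% and 26.9% for 22 nt, 17.6%, 7.06%, 4.13% and 4.77% for 23 nt and 32.5%, 38.4%, 19.5% and 45.5% for 24 nt.

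The ratio of 23 to 24 nt reads to 20 to 22 nt reads was 1.00, 0.834, 0.309 and 1.01 in IE, C1, C4 and C10. Without the reads of no class, again a smaller denominator, the shares in the same order were 0.0757%, 0.623%, 0.125% and 0.101% for tasiRNAs, 18.9%, 12.0%, 10.3% and 7.73% for cdsRNAs, 6.29%, 12.9%, 27.5% and 25.7% for miRNAs, 27.8%, 27.5%, 18.8% and 21.2% for lincRNAs and 46.9%, 46.9%, 43.3% and 45.3% for rasiRNAs.

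Higher and lower in C1 against IE were 25 and 57 on the miRNA table scale, 42 and 44 with median-of-ratios factors, 27 and 52 with TMM, 29 and 47 on the miRNA class scale and 24 and 11 with 1 entry per family and arm, and 74 and 55 with no minimum, 49 and 15 with a minimum of 100, 71 and 47 over all deposited entries and 51 and 16 thinned. In C4 against IE these numbers were 20 and 58 on the miRNA table scale, 52 and 41 with median-of-ratios factors, 20 and 56 with TMM, 33 and 52 on the miRNA class scale and 27 and 8 with 1 entry per family and arm, and 90 and 32 with no minimum, 54 and 11 with a minimum of 100, 86 and 36 over all deposited entries and 68 and 13 thinned. For C10 against IE they were 28 and 71 on the miRNA table scale, 42 and 48 with median-of-ratios factors, 40 and 50 with TMM, 26 and 74 on the miRNA class scale and 29 and 10 with 1 entry per family and arm, and 75 and 64 with no minimum, 58 and 25 with a minimum of 100, 78 and 57 over all deposited entries and 48 and 23 thinned. C4 against C1 had 36 and 38 on the miRNA table scale, 45 and 30 with median-of-ratios factors, 34 and 42 with TMM, 43 and 37 on the miRNA class scale and 23 and 11 with 1 entry per family and arm, and 81 and 39 with no minimum, 49 and 24 with a minimum of 100, 84 and 35 over all deposited entries and 63 and 24 thinned. The numbers for C10 against C1 were 26 and 59 on the miRNA table scale, 35 and 40 with median-of-ratios factors, 37 and 39 with TMM, 24 and 70 on the miRNA class scale and 18 and 11 with 1 entry per family and arm, and 44 and 70 with no minimum, 31 and 32 with a minimum of 100, 40 and 57 over all deposited entries and 22 and 31 thinned. Those for C10 against C4 were 44 and 48 on the miRNA table scale, 44 and 48 with median-of-ratios factors, 63 and 23 with TMM, 27 and 66 on the miRNA class scale and 8 and 23 with 1 entry per family and arm, and 19 and 103 with no minimum, 16 and 56 with a minimum of 100, 21 and 90 over all deposited entries and 10 and 58 thinned. The scalings move this balance by their construction. In the pairs with IE the share of miRNA reads differed, at 3.44% in IE and 17.0% in C4. In C10 and C4 the shares were closer, at 15.0% and 17.0%. The sum of the miRNA table differed more there, at 2.81 and 5.01 times the miRNA class reads. A minimum of 100 and 1 entry per family and arm leave fewer entries to count. The deposited entries count entries with identical counts more than once. Thinning lowers the counts, so that fewer entries reach the minimum count. Both were run at the same scaling, and whether this accounts for all of their differences was not tested.

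Each list median, as a log2 ratio, is given next on the miRNA table scale, with median-of-ratios factors and with the most abundant entry of each family in place of the family sum. The latter median leaves out entries below the minimum count in the pair. In C10 against C4 these included miR395b-3p and miR399e-5p of the nutrient list. In C1 against IE they were −0.43, 0.19 and 1.07 for the auxin list, 0.0861, 0.71 and 1.67 for the developmental list, −2.42, −1.79 and −1.34 for the nutrient list, 1.53, 2.16 and 2.95 for the silencing list and 0.33, 0.95 and 1.64 for the other list. For C4 against IE they were 0.38, 1.65 and 2.54 for the auxin list, −1.03, 0.24 and 2.78 for the developmental list, −0.57, 0.70 and 2.39 for the nutrient list, 0.36, 1.63 and 3.34 for the silencing list and −1.43, −0.16 and 1.56 for the other list. In C10 against IE they were −1.23, 0.0545 and 0.60 for the auxin list, −0.94, 0.35 and 1.13 for the developmental list, 0.14, 1.43 and 1.86 for the nutrient list, 0.82, 2.11 and 2.79 for the silencing list and −1.60, −0.31 and 0.88 for the other list. For C4 against C1 they were 0.11, 0.75 and 2.30 for the auxin list, −1.47, −0.82 and 0.81 for the developmental list, −0.0902, 0.55 and 3.0 for the nutrient list, −1.17, −0.53 and 0.39 for the silencing list and −1.75, −1.11 and −0.07 for the other list. In C10 against C1 they were −0.95, −0.29 and −0.36 for the auxin list, −1.25, −0.59 and −0.57 for the developmental list, 0.77, 1.43 and 1.71 for the nutrient list, −0.71, −0.05 and −0.16 for the silencing list and 0.96, 1.62 and 1.51 for the other list. For C10 against C4 they were −1.29, −1.27 and −2.53 for the auxin list, 0.34, 0.36 and 0.19 for the developmental list, 1.69, 1.71 and 0.36 for the nutrient list, 0.46, 0.48 and −0.55 for the silencing list and 0.73, 0.75 and −0.51 for the other list. Of the list medians of at least 2-fold, that of the developmental list in C4 against IE turned direction on the miRNA table scale, as did that of the nutrient list in C4 against IE and in C4 against C1 and, with median-of-ratios factors too, that of the other list in C4 against IE.

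Entries at least 2-fold higher and lower than IE in all 3 callus libraries were 8 and 34 on the miRNA table scale, 10 and 20 with median-of-ratios factors, 8 and 27 with TMM, 9 and 25 on the miRNA class scale and 14 and 5 with 1 entry per family and arm.

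Of 157 ratios of named miRNAs of at least 2-fold with the added 0.5, 19 turned direction on the miRNA table scale, 14 with TMM and 1 with median-of-ratios factors, and the others kept theirs. The log2 ratios that turned in C1 against IE were −0.29 for miR156b-5p and −0.0214 for miR394a-5p on the miRNA table scale, and −0.10 for miR156b-5p with TMM. Those of C4 against IE were −1.24 for miR167a-5p, −0.16 for miR319d-3p, −1.11 for miR390a-5p, −0.54 for miR397b-5p, −0.24 for miR398b-3p, −0.57 for miR408a and −1.01 for miR528b-5p on the miRNA table scale, and −1.21 for miR167a-5p, −0.12 for miR319d-3p, −1.08 for miR390a-5p, −0.50 for miR397b-5p, −0.21 for miR398b-3p, −0.53 for miR408a and −0.97 for miR528b-5p with TMM. The ones of C10 against IE were −0.34 for miR156b-5p, −0.30 for miR159b-3p, −0.45 for miR160c-5p, −0.55 for miR169c-5p, −0.67 for miR390a-5p and −0.79 for miR827-3p on the miRNA table scale. Ratios that turned in C4 against C1 were −0.13 for miR160c-5p, −0.35 for miR166a-3p and −0.17 for miR319d-3p on the miRNA table scale, and −0.29 for miR160c-5p, −0.50 for miR166a-3p and −0.33 for miR319d-3p with TMM. And those of C10 against C4 were 0.0143 for miR162-3p on the miRNA table scale, and 0.26 for miR160c-5p, 1.05 for miR162-3p and 0.0387 for miR827-3p with TMM, and 0.0338 for miR162-3p with median-of-ratios factors.

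Among loci of at least 1 RPM, the classes of 20, 21, 22, 23 and 24 nt and the loci with no called size held 0.150%, 1.81%, 6.35%, 0.222%, 88.2% and 3.23% of the loci. Weighted by reads, the same classes held 2.42%, 18.2%, 26.6%, 0.401%, 48.8% and 3.59%.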

Other observations

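The rules for testing the adaptor and the mix on rank correlations were written before the result was seen, without the bootstrap interval given below. The test of embryo against callus and all tests on the tasiRNA share were chosen only after the result was seen.

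The balance of the 2 arms of a precursor differed between libraries. For 45 precursors with both arms compared, the log2 ratio of 5p to 3p reads had a median range of 3.84 over the 4 libraries, and for MIR827, MIR390a and MIR390b the arm over 2-fold the more abundant in 1 library was over 2-fold the less abundant in another. MIR390a and MIR390b had identical counts in both arms, so they repeat the same values, with 30 reads of 5p and 75 of 3p in C4. Other precursors of a family can share reads too, so the 45 are not independent. Smaller switches, such as in MIR398b, were not counted. For MIR156i, chosen after its values were seen, the 5p arm had 5329, 9836, 23402 and 104111 reads in IE, C1, C4 and C10 and the 3p arm 903, 9, 9 and 26. The 5p sequence is shared by several precursors of miR156, so its reads need not come from MIR156i alone, and this ratio within a library does not depend on the scaling.

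The libraries were compared by the rank correlation of miRNA levels. If the 3' adaptor ordered the libraries, the 2 pairs that share an adaptor would correlate best, and the mean rho of these pairs lay 0.0239 below that of the pairs that share a sequencing mix (difference −0.0239, 95% bootstrap interval over families −0.0558 to 0.00883). For the mix the difference is the same with the other sign, 0.0239, and its interval includes 0, so neither can be excluded. The lowest rho of a callus pair was 0.0656 above the highest rho of a pair with IE (−0.0490 to 0.144), an order that a tissue difference may produce but that the single embryo library leaves open. The mean over callus pairs exceeded that over pairs with IE by 0.101 (0.0143–0.187), with families rather than libraries as the units drawn.

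The tasiRNA share in C1 was 8.19-fold that in IE (7.64–8.79). C1 and IE shared the sequencing mix and differed in the adaptor. C10, with the adaptor of C1, had 0.173 times the share of C1, so the adaptor alone does not set the share across the libraries. Whether the adaptor raised C1 above IE cannot be told, since C10 also differed from C1 in mix and culture age. A candidate explanation is the level of miR390, which sets off tasiRNAs, because the libraries had the same order by tasiRNA share and by miR390a-5p RPM in 4 of 4 cases. This is 1 of 24 possible orders, which is no measure of chance, since the comparison was chosen after the values were seen. The match holds per the clean reads. On the miRNA table and TMM scales miR390a-5p was lower in C4 than in IE (log2 ratios −1.11 and −1.08), so the order of its levels depends on the scaling. The order of C4 and C10 rests on intervals of miR390a-5p that overlap, and summed over its arms miR390 was higher in C4 than in C1. TasiRNA reads per miR390a-5p read were 25.6, 31.8, 13.6 and 15.1 in IE, C1, C4 and C10, and whether callus age sets either level was not tested.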
